A study of Mus musculus with 18 samples.

How the data were processed

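The files held counts of reads per gene symbol for 18 libraries, 2 in each of 9 groups. According to the submitters' notes, the counts deposited by the authors came from reads aligned to mm10 with TopHat2 2.0.7 and processed with Cufflinks 2.0.2, HTSeq 0.6.0 and Cuffdiff 2.0.2. The notes did not state the order of these tools, the strand setting or the annotation. Gene counts per library (M) were 24.36 and 27.24 for ES control, 44.79 and 20.92 for GW3965, 29.2 and 22.38 for LG268, and 19.48 and 20.54 for both ligands. They were 25.16 and 29.95 at day 8, 22.67 and 34.08 at day 16, 29.82 and 29.59 at day 16 with GW3965, 22.53 and 16.75 at day 17, and 20.82 and 21.94 at day 17 with GW3965.

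Each file ended with 5 HTSeq summary lines, which were kept out of the gene counts. Reads given to no gene made up 62.77 to 65.92% of the 14 other files and 42.14 to 43.36% of the day 17 files. There 23.18 to 29.52 M reads were listed as aligned more than once. With those set aside, 63.4 to 63.61% of the day 17 reads had no gene. Ambiguous reads made up 0.1011 to 0.2613%, and the 10 largest genes held 2.766 to 4.928% of gene counts. Symbols were matched to GENCODE M21 for positions, GC content and length (98.309% matched, 1247 of them by a synonym), and the share of each gene's 50-mers found in another gene was computed for 22380 symbols.

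Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passing filterByExpr were kept (17166), and 2530 had no count in any library. Libraries were scaled by TMM (factors 0.9124 to 1.108), and 1 quasi-likelihood fit of edgeR with 9 groups was used for 15 comparisons (9 residual and 10.41 prior degrees of freedom, common biological variation 6.471%, median 6.92%). The comparisons were 6 pairwise ones and 1 interaction among ES groups, 3 steps of the time course, 2 of GW3965 at days 16 and 17, and 3 between GW3965 responses. Tests were two-sided, p values were adjusted by Benjamini-Hochberg within each comparison, and a gene changed at an adjusted p below 0.05 with no minimum fold. Intervals and floors cover counting error, SE also the fitted spread, and none that between cultures if replicates were technical. Replicate numbers carried no shared signal between groups (36 pairs, correlation -0.096 to 0.0691), so libraries were not paired.

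Before the data were examined, 29 gene lists were fixed, and the 27 with 5 or more tested members were tested with camera on voom values at a preset correlation of 0.01 and with an estimated correlation. They were LXR, retinoid and PPAR targets, cholesterol and fatty acid synthesis, pluripotency, primed epiblast, neural progenitor, pan-neuronal, glutamatergic, GABAergic, dopaminergic, cholinergic and motor, astrocyte, oligodendrocyte, anterior neural, Hox, endoderm, mesoderm, muscle, mesenchyme, neural crest and Schwann, endothelial and blood, cell cycle, stress and apoptosis, immediate early, and nuclear receptor genes. Of 12 microglia and leukocyte genes 4 were tested, and of 13 mitochondrial transcripts 0 were in the files. No comparison called the cholinergic and motor, muscle, endothelial and blood, or neural crest and Schwann list. From ES control to day 8 these had 9, 7, 6 and 7 higher and 1, 2, 3 and 2 lower members (camera adjusted p = 0.0545, 0.547, 0.48 and 0.105).

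Named genes followed a fixed rule. Per comparison these were the 4 largest rises and falls (3 for response differences and for comparisons with a ligand as reference) at 5 CPM or more, with both libraries of 1 group above both of the other. Up to 3 called members of lists with a call or 3 called members were added, and fixed sets of 6 genes were always reported. Some genes under this rule were left out of the text, among them Saa3, Cyp2j13, C1qtnf3 and Cdh26 in the response differences, near 0 in some groups and lost in several settings. Where a group had 3 counts or fewer, a fold was given as a floor of 3 counts per library or with a counting interval.

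Alternatives set before the files were opened were no filter, a stricter filter (1 CPM in 4 libraries), DESeq2 size factors, the DESeq2 Wald test, limma-voom, a fit of the groups compared, a replicate block, leaving out 1 library, and the both-ligand libraries as reference. Added after the data were seen were genes with under 1% of shared 50-mers, a fit without the 4 day 17 libraries, and offsets for GC content and length. The code was tested on simulated data. For LG268 in ES cells 24, 82, 88 and 100% of genes planted at 1.25, 1.5, 2 and 4-fold were recovered with 3 of 164 calls false (1.83%), and for GW3965 at day 16 38, 64, 92 and 100% with 18 of 177 false (10.2%). With genes drawn independently a planted list was called (adjusted p = 1.5e-43 and 3.68e-38) and 0 of 20 unchanged were. Correlation within lists was untested. Planted GC trends called 5470 and 6225 unchanged genes, and 8 and 14 after offsets. Splicing, reads with no gene and sequence-level checks were left out, as the files held gene counts alone.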

Results

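RNA of wild type E14 mouse embryonic stem (ES) cells and of cultures differentiated from them was sequenced in 18 libraries, and reads were counted per gene symbol. The libraries fell into 9 groups of 2. Undifferentiated ES cells were left as control or given GW3965, LG268 or both ligands for 24 h. Differentiated cultures were taken at days 8, 16 and 17 without ligand, and at days 16 and 17 with GW3965. GW3965 activates the liver X receptors (LXR), which control cholesterol and fatty acid genes, and LG268 activates the retinoid X receptors (RXR), with which LXR and the retinoic acid receptors pair. Each ligand was used at 1 µM, and neural differentiation ran through embryoid bodies (floating cell aggregates) with 5 µM retinoic acid over 4 days. The sample labels gave no duration for GW3965 in the differentiated cultures, while the names of the deposited files read as treatment from day 8 for the day 16 group and for 24 h for the day 17 group. The labels did not say whether the replicates were separate cultures, so the 2 libraries of a group may be technical repeats.

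Gene counts per library ran from 16.75 to 44.79 M with a median of 23.52 M. Between 17407 and 18775 genes had a count in a library, and 17166 genes passed the filter and were tested. In the 4 day 17 libraries 31.84 to 33.53% of the reads in the files stood apart as aligned more than once, while that number was 0 in the 14 other files. Levels below are mean counts per M (CPM) ± SD of 2 libraries (n = 2), and log2 fold changes carry their SE. Adjusted p values come from an edgeR fit of all 18 libraries, and list tests from camera. Positions are those of the GRCm38 (mm10) annotation.

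**Figure D1:**
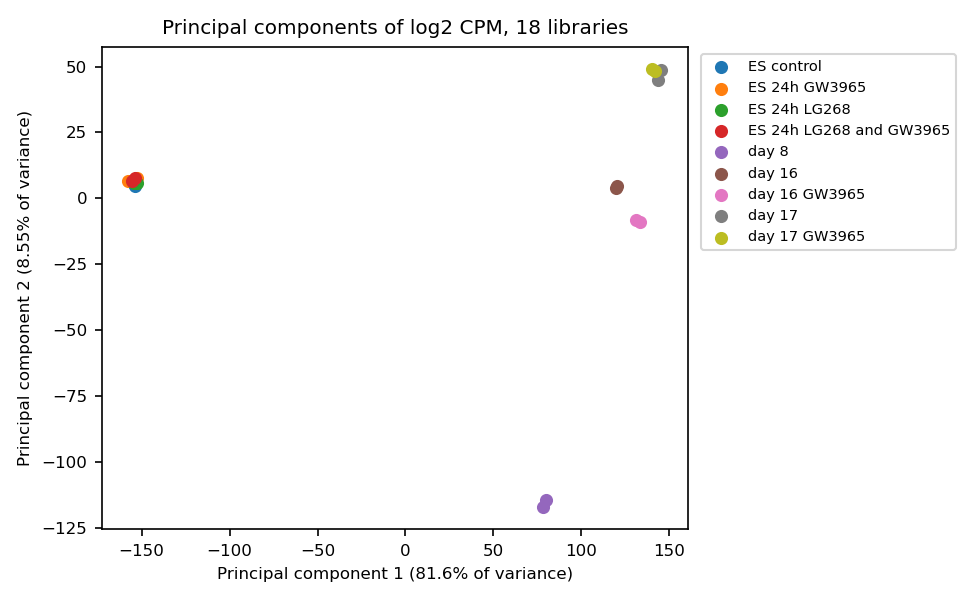
Each point is 1 library, placed by the first principal components of log2 CPM (81.6% of variance on the horizontal and 8.55% on the vertical axis) and coloured by group. The 8 ES libraries sat between -157.5 and -152.8 on the horizontal axis, the day 8 libraries at 78.29 and 79.96, and the day 16 and day 17 libraries between 119.7 and 145.5.

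ES cells given GW3965 were compared with ES control. Genes of cholesterol export and fatty acid synthesis rose. Abca1 (chromosome 4, 53030787 to 53159895), which moves cholesterol out of the cell, rose 41.4-fold from 8.15 ± 0.907 to 336 ± 12.4 CPM (log2 5.37 ± 0.101, adjusted p = 3.08e-18). Abcg1 (chromosome 17, 31057675 to 31117988), another sterol transporter, rose 8.43-fold to 198 ± 0.2 CPM (adjusted p = 2.13e-14). Srebf1 (chromosome 11, 60199089 to 60222581), which encodes a transcription factor of lipid synthesis, rose 5.51-fold to 833 ± 29.1 CPM (adjusted p = 2.5e-11). Mylip (chromosome 13, 45389742 to 45412022), whose product marks the LDL receptor for degradation, rose 5.14-fold from 10.2 ± 0.915 to 52.5 ± 1.45 CPM (adjusted p = 1.48e-11).

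Of 18 tested LXR targets 11 rose and 0 fell under GW3965 (12 and 0 adjusted over the list alone), with a camera adjusted p = 5.83e-75. Of 16 fatty acid synthesis genes 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a camera adjusted p = 1.6e-62. Both calls held with an estimated correlation (adjusted p = 1.68e-05 and 2.78e-05), and 4 genes stood on both lists. Fasn, the fatty acid synthase gene, rose 4.73-fold from 896 ± 10.5 to 4236 ± 174 CPM (log2 2.24 ± 0.0762), and the desaturase gene Scd2 rose 3.81-fold to 4598 ± 126 CPM. Acaca, which encodes an acetyl-CoA carboxylase, rose 2.40-fold to 193.5 ± 1.24 CPM, with 31.4% of its 50-mers (stretches of 50 bases) also found in a gene elsewhere. Of 23 cholesterol synthesis genes 2 rose and 0 fell (7 and 2 adjusted over the list alone), among them Insig1, 1.44-fold higher (adjusted p = 0.000657). The list's camera adjusted p = 0.00869 was lost with an estimated correlation (adjusted p = 0.988). Mesoderm genes moved lower as a group (median log2 -0.23, camera adjusted p = 6.55e-05, adjusted p = 0.0103 with an estimated correlation), with 0 of 13 called. Of 24 pluripotency genes 0 were called (camera adjusted p = 5.89e-05, adjusted p = 0.529 with an estimated correlation). The retinoid target genes Rarb (log2 0.08 ± 0.329, adjusted p = 1.0) and Cyp26a1 (log2 -0.22 ± 0.185, adjusted p = 1.0) did not pass.

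In all, 55 genes changed with GW3965 in ES cells, 53 higher and 2 lower, and 16 by 2-fold or more. The 2 falls were Enpp2, 1.40-fold lower (adjusted p = 0.0155), and Ccnd2, 1.30-fold lower (adjusted p = 0.0199). Without ES control replicate 1 or 2 the count was 28 or 33, and without GW3965 replicate 1 it was 31. It was 164 with no filter and 369 in a fit of the 4 libraries compared. The call of Enpp2 ended without ES control replicate 1 or 2 or GW3965 replicate 1 (adjusted p = 0.0584, 0.312 and 0.573), and that of Ccnd2 without ES control replicate 1 or 2 or GW3965 replicate 2 (adjusted p = 0.202, 0.226 and 0.325) and with limma-voom (adjusted p = 0.125).

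**Figure D2:**
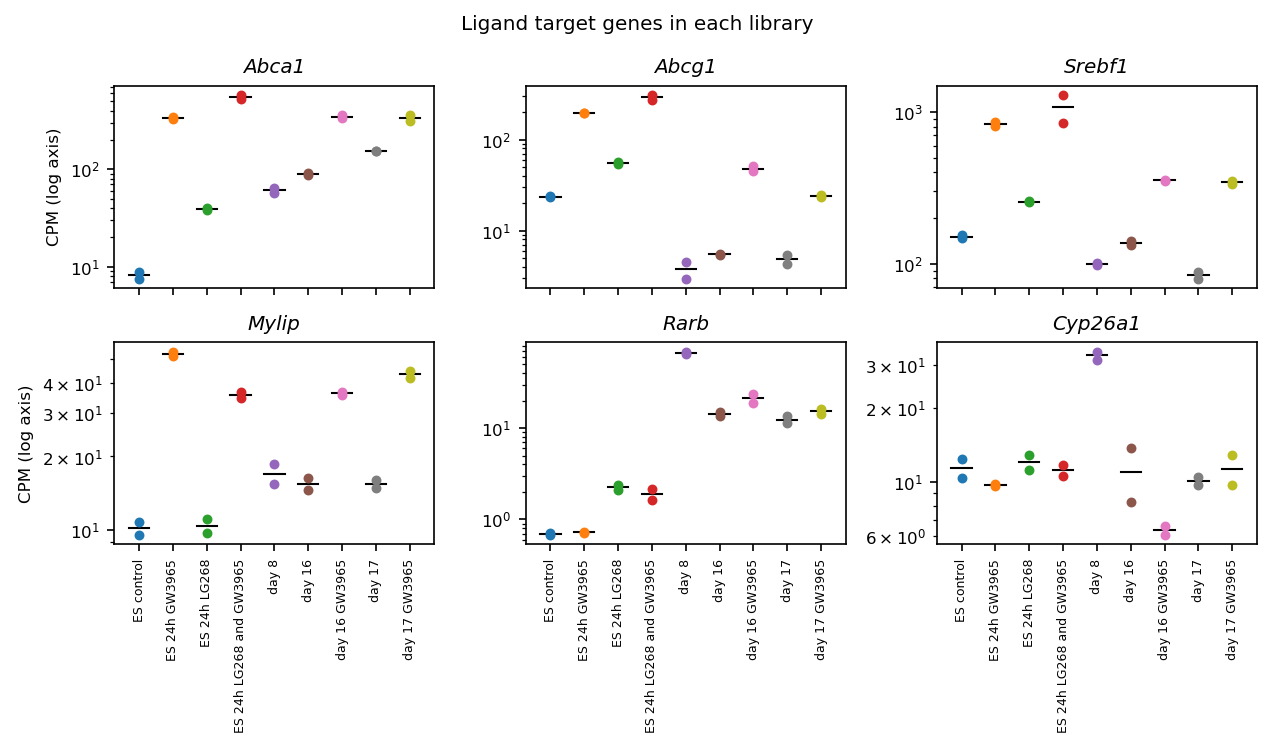
CPM on a log axis of 4 LXR targets and 2 retinoid targets in each of the 18 libraries; points are libraries and lines are group means. Abca1 lay at 8.15 CPM in ES control and between 336 and 554 CPM in the groups given GW3965, while Rarb was at 0.688 CPM in ES control and 67.2 CPM at day 8.

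ES cells given LG268 were compared with ES control. LXR targets and retinoid targets rose, and genes of mesoderm fell. Abca1 rose 4.80-fold to 39 ± 1.27 CPM (log2 2.26 ± 0.106, adjusted p = 4.97e-11), Scd2 rose 2.58-fold to 3111 ± 16.5 CPM, and Abcg1 rose 2.37-fold to 55.7 ± 1.82 CPM. Rarb, the retinoic acid receptor beta gene (chromosome 14, 16430839 to 16819156), rose 3.27-fold from 0.688 ± 0.0223 to 2.24 ± 0.203 CPM (adjusted p = 0.00202, but 0.0934 with limma-voom). Plin2, a lipid droplet coat gene and PPAR target, rose 1.84-fold to 142 ± 1.09 CPM (adjusted p = 5.76e-06).

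Under LG268, 8 of 18 LXR targets rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 1.44e-24). Fatty acid synthesis genes rose in 8 of 16 with 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 1.44e-24). Acaca rose 1.61-fold (adjusted p = 1.77e-06), Acsl3 1.61-fold (adjusted p = 4.66e-05) and Srebf1 1.70-fold (adjusted p = 0.00123). Mylip stayed at 10.4 ± 1.02 CPM against 10.2 ± 0.915 (adjusted p = 0.991). Among 22 retinoid targets 6 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 9.78e-12), with Meis2 2.32-fold higher (adjusted p = 0.000218). Cyp26a1, which degrades retinoic acid, did not pass (log2 0.09 ± 0.184, adjusted p = 0.955). Of 17 PPAR targets 3 rose and 0 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.000548). Mesoderm genes fell in 4 of 13 with 0 higher (8 lower adjusted over the list alone, camera adjusted p = 1.21e-10), with Eomes 1.805-fold lower (adjusted p = 0.000608). These 5 list calls held with an estimated correlation (adjusted p = 0.000797, 0.000797, 0.00561, 0.0229 and 0.000797). For cholesterol synthesis 1 of 23 genes rose (1 adjusted over the list alone), and the camera adjusted p = 0.0016 became adjusted p = 0.616 with an estimated correlation. Of 25 Hox genes 1 rose (2 adjusted over the list alone), and the camera adjusted p = 0.0181 became adjusted p = 0.532 with an estimated correlation. Of primed epiblast genes, active around implantation, Fgf5 fell 2.15-fold to 26 ± 0.545 CPM and Lefty1 rose 1.79-fold to 143 ± 5.66 CPM. The list was not called. Of the 50-mers of Lefty1 18.7% were shared with a gene elsewhere.

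LG268 changed 146 genes in ES cells, 89 higher and 57 lower, and 31 by 2-fold or more. Fgfbp3, which binds fibroblast growth factors, was 3.01-fold higher (adjusted p = 2e-05). The largest falls were in Lhx1, 3.31-fold to 6.08 ± 1.17 CPM (adjusted p = 0.000117), Enpp2, 2.54-fold to 21.6 ± 0.0709 CPM (adjusted p = 7.27e-08), Evx1, 3.32-fold (adjusted p = 0.00291), and Cer1, 3.21-fold (adjusted p = 0.00975). Without ES control replicate 1 or 2 the count was 42 or 62, and without LG268 replicate 1 or 2 it was 70 or 42. It was 336 with no filter, 227 with the DESeq2 Wald test and 843 in a fit of the 4 libraries compared. The call of Evx1 ended without ES control replicate 1 or LG268 replicate 2 (adjusted p = 0.064 and 0.107), and that of Cer1 without ES control replicate 1 or LG268 replicate 1 or 2 (adjusted p = 0.214, 0.193 and 0.0988).

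A direct comparison of LG268 with GW3965 in ES cells showed on which genes the ligands differed. LXR targets were lower with LG268, as Abca1 at 39 ± 1.27 against 336 ± 12.4 CPM (8.62-fold, adjusted p = 3.47e-15) and Mylip at 10.4 ± 1.02 against 52.5 ± 1.45 CPM (5.04-fold, adjusted p = 3.02e-11). Abcg1 was 3.55-fold and Srebf1 3.24-fold lower with LG268 (adjusted p = 6.19e-11 and 1.77e-08). Retinoid targets were higher with LG268, as Meis2 at 6.37 ± 0.175 against 1.52 ± 0.198 CPM (4.06-fold, adjusted p = 5.43e-07). Ntrk2, a neurotrophin receptor gene, was 2.85-fold higher with LG268 (adjusted p = 0.00263), which ended without GW3965 replicate 1 or LG268 replicate 2 (adjusted p = 0.0525 and 0.0751) and with limma-voom (adjusted p = 0.113).

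Between the ligands 10 of 18 LXR targets were lower and 0 higher with LG268 (11 and 0 adjusted over the list alone, camera adjusted p = 1.22e-42). So were 7 of 16 fatty acid synthesis genes (10 and 0 adjusted over the list alone, camera adjusted p = 1.69e-25). Fasn was at 1328 ± 37.8 CPM with LG268 (3.19-fold lower, adjusted p = 2.1e-11). Of 22 retinoid targets 4 were higher and 0 lower with LG268 (8 and 0 adjusted over the list alone, camera adjusted p = 1.94e-10). Of 17 PPAR targets 3 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.000201). Of 13 mesoderm genes 0 were called (6 lower adjusted over the list alone, camera adjusted p = 3.46e-05). These 5 calls held with an estimated correlation (adjusted p = 0.000179, 0.00112, 0.00895, 0.0176 and 0.00895). The other 3 did not. Of 24 pluripotency genes 2 were lower and 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 4.45e-09, adjusted p = 0.106 with an estimated correlation). Of 25 Hox genes 2 were higher (4 adjusted over the list alone, camera adjusted p = 3.46e-05, adjusted p = 0.135 with an estimated correlation). Of 19 nuclear receptor genes 1 was higher (2 adjusted over the list alone, camera adjusted p = 0.0284, adjusted p = 0.181 with an estimated correlation). That gene was Rarb, 3.08-fold higher with LG268 (adjusted p = 0.00227), whose call ended without GW3965 replicate 1 (adjusted p = 0.109) or LG268 replicate 1 (adjusted p = 0.0902) and with limma-voom (adjusted p = 0.0943). Cyp26a1 did not pass (log2 0.31 ± 0.184, adjusted p = 0.735). The comparison held 103 changed genes, 49 higher and 54 lower with LG268 (51 and 44 with DESeq2 size factors), and 17 by 2-fold or more. Without GW3965 replicate 1 or 2 the count was 32 in each case, and without LG268 replicate 1 or 2 it was 29 or 35. It was 266 with no filter, 175 with the DESeq2 Wald test and 892 in a fit of the 4 libraries compared.

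ES cells given both ligands were compared with ES control and with each ligand alone. Abca1 reached 554 ± 32 CPM with both ligands, 68.1-fold above ES control (adjusted p = 3.55e-19), 14.2-fold above LG268 alone (adjusted p = 9.64e-17) and 1.65-fold above GW3965 alone (adjusted p = 1.29e-05). Abcg1 reached 292 ± 22.9 CPM, 12.4-fold above ES control (adjusted p = 8.95e-16) and 1.48-fold above GW3965 alone (adjusted p = 0.000543). Mylip took the other course, at 35.6 ± 1.55 CPM 3.49-fold above ES control (adjusted p = 1.14e-09) but 1.47-fold below GW3965 alone (adjusted p = 0.00195). Srebf1 rose 7.09-fold over ES control to 1071 ± 310 CPM (adjusted p = 2.46e-12). Its 1.29-fold excess over GW3965 alone (adjusted p = 0.0417) ended without both-ligand replicate 2 (adjusted p = 0.817) or without GW3965 replicate 1 or 2 (adjusted p = 0.141 and 0.211), and in fits of the 4 libraries compared (adjusted p = 0.226) or without the day 17 libraries (adjusted p = 0.0524). Fgfbp3 rose 5.505-fold over ES control (adjusted p = 4.01e-09). The name of this group's deposited file reads as a control, while its labels give both ligands.

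Against ES control, 12 of 18 LXR targets and 13 of 16 fatty acid synthesis genes rose with both ligands, with 0 lower (12 and 14 adjusted over the list alone, camera adjusted p = 5.61e-35 and 3.32e-36). Fasn rose 5.15-fold to 4612 ± 493 CPM, Scd2 5.46-fold to 6591 ± 209 CPM, and Acaca 3.74-fold to 302.5 ± 14.2 CPM. Of 17 PPAR targets 5 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.000693), with Plin2 2.165-fold higher. Mesoderm genes fell in 6 of 13 with 0 higher (7 adjusted over the list alone, camera adjusted p = 7.84e-07), with Eomes 1.93-fold lower (adjusted p = 6.4e-05). These 4 list calls held with an estimated correlation (adjusted p = 0.000254, 0.000254, 0.0318 and 0.00277). Retinoid targets rose in 8 of 22 with 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 2.85e-05, adjusted p = 0.0577 with an estimated correlation), with Crabp2, a retinoic acid binding protein gene, 2.35-fold higher. Rarb was 2.71-fold higher (adjusted p = 0.00376, but 0.067 without both-ligand replicate 1, 0.0597 with limma-voom and 0.0779 in a fit of the 4 libraries compared), and Cyp26a1 did not pass (log2 -0.03 ± 0.19, adjusted p = 0.966). Pluripotency genes fell in 7 of 24 and rose in 2 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.779 with an estimated correlation), with Klf4 2.19-fold lower at 12.8 ± 2.22 CPM. Cholesterol synthesis genes rose in 7 of 23 and fell in 4 (12 and 5 adjusted over the list alone, camera adjusted p = 0.000453, adjusted p = 0.75 with an estimated correlation), with Pmvk 1.71-fold higher and Sqle 1.17-fold lower (adjusted p = 0.00435, but 0.0941 in that smaller fit). The largest falls were Evx1, 3.82-fold (adjusted p = 0.000439), Lhx1, 3.33-fold (adjusted p = 5.2e-05), Fgf5, 3.16-fold (adjusted p = 4.83e-07), and Enpp2, 2.73-fold (adjusted p = 5.46e-09).

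With both ligands 1939 genes differed from ES control, 829 higher and 1110 lower, and 158 by 2-fold or more. Without ES control replicate 1 or 2 the count was 718 or 780, without both-ligand replicate 1 it was 727, and in a fit of the 4 libraries compared it was 427. The split turned with DESeq2 size factors (1000 higher, 923 lower), the DESeq2 Wald test (1099, 1012) and that smaller fit (270, 157). The 2 libraries given both ligands differed from each other more than those of the other ES groups, with a chi-square of 11.48 per gene against 2.934 to 3.514.

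What GW3965 added to LG268 was read from both ligands against LG268 alone. LXR targets and fatty acid synthesis genes rose further. LXR targets rose in 12 of 18 cases and fatty acid synthesis genes in 11 of 16, with 0 lower (12 and 12 adjusted over the list alone, camera adjusted p = 7.95e-36 and 2.56e-35). Both held with an estimated correlation (adjusted p = 0.000274 each). Abcg1 rose 5.24-fold (adjusted p = 6.99e-13), Srebf1 4.17-fold (adjusted p = 4.62e-10), Mylip 3.42-fold (adjusted p = 2.49e-09) and Lpcat3, a phospholipid remodelling gene, 2.71-fold to 391 ± 13.4 CPM (adjusted p = 6.99e-13). Falls were largest in H1fx, 2.64-fold (adjusted p = 0.00656), Rplp2, 2.07-fold (adjusted p = 0.000461), and Bola1, 2.06-fold (adjusted p = 0.0305). The calls of H1fx and Rplp2 ended in a fit of the 4 libraries compared (adjusted p = 0.17 and 0.0673). That of H1fx also ended without LG268 replicate 2 (adjusted p = 0.0948) or both-ligand replicate 1 (adjusted p = 0.0504), and that of Bola1 without LG268 replicate 1 or 2 or both-ligand replicate 1 (adjusted p = 0.145, 0.158 and 0.36). Rarb and Cyp26a1 did not pass (log2 -0.27 ± 0.234 and -0.11 ± 0.189, adjusted p = 0.584 and 0.803). In total 722 genes changed, 280 higher and 442 lower, and 53 by 2-fold or more. Without LG268 replicate 1 or 2 the count was 123 or 103, without both-ligand replicate 1 or 2 it was 113 or 2379, in a fit of the 4 libraries compared it was 56, and with no filter 1373. Higher and lower genes were 359 and 351 with DESeq2 size factors, 564 and 495 with the Wald test, and 53 and 3 in the smaller fit.

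What LG268 added to GW3965 was read from both ligands against GW3965 alone. Part of the LXR target, fatty acid synthesis and PPAR target lists was higher, and part of the mesoderm list lower. Meis2 rose 3.20-fold (adjusted p = 2.34e-05) and Rsad2, an interferon-induced gene, 3.56-fold to 6.79 ± 0.709 CPM (adjusted p = 0.00113). LXR targets rose in 8 of 18 and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 6.78e-08), with Lpcat3 2.04-fold higher. Fatty acid synthesis genes rose in 6 of 16 (7 adjusted over the list alone, camera adjusted p = 1.62e-12), with Acsl3 1.90-fold higher. PPAR targets rose in 4 of 17 (4 adjusted over the list alone, camera adjusted p = 0.000794), with Plin2 1.91-fold higher. Mesoderm genes fell in 6 of 13 (7 adjusted over the list alone, camera adjusted p = 0.000286). These 4 calls held with an estimated correlation (adjusted p = 0.0266, 0.0266, 0.0331 and 0.0266). Pluripotency genes fell in 9 of 24 (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.69e-06, adjusted p = 0.217 with an estimated correlation), with Klf4 2.045-fold lower.

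The other list calls of that comparison were lost with an estimated correlation. Retinoid targets rose in 7 of 22 (8 adjusted over the list alone, camera adjusted p = 0.000155, adjusted p = 0.0875 with an estimated correlation). Cholesterol synthesis genes rose in 3 of 23 and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.929 with an estimated correlation). Of 25 Hox genes 1 rose (1 adjusted over the list alone, camera adjusted p = 0.0446, adjusted p = 0.733 with an estimated correlation). Immediate early genes fell in 3 of 13 (5 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.87 with an estimated correlation). Rarb was 2.56-fold higher (adjusted p = 0.00493, but 0.0725 without GW3965 replicate 1, 0.104 without both-ligand replicate 1, 0.0553 with limma-voom and 0.0939 in a fit of the 4 libraries compared), and Cyp26a1 did not pass (log2 0.20 ± 0.19, adjusted p = 0.58). Falls were largest in Chga, 3.07-fold (adjusted p = 0.000577), H1fx, 2.87-fold (adjusted p = 0.00196, but 0.0884 in that smaller fit), and Lhx1, 2.83-fold (adjusted p = 0.000485). In total 1831 genes changed, 632 higher and 1199 lower, and 95 by 2-fold or more. Without GW3965 replicate 1 or 2 the count was 336 or 842, without both-ligand replicate 1 or 2 it was 325 or 3077, in a fit of the 4 libraries compared it was 111, and with GC and length offsets 1190. Higher and lower genes were 952 and 938 with DESeq2 size factors, 1121 and 1040 with the Wald test, and 66 and 45 in the smaller fit.

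The interaction tested whether both ligands together gave less or more than the sum of their log2 effects. Abca1 lay below the sum by a log2 of -1.54 ± 0.131 (adjusted p = 4.49e-06), and Scd2 by -0.85 ± 0.0766 (adjusted p = 6.91e-06). Abcg1 lay at -0.69 ± 0.13 (adjusted p = 0.0438), the transcription factor gene Junb at -1.59 ± 0.302 (adjusted p = 0.0438), Tmem160 at -1.32 ± 0.254 (adjusted p = 0.0444), and Lpcat3 above the sum at 0.42 ± 0.0762 (adjusted p = 0.0376). Mylip (-0.59 ± 0.156, adjusted p = 0.11), Srebf1 (-0.40 ± 0.16, adjusted p = 0.272), Rarb (-0.35 ± 0.404, adjusted p = 0.765) and Cyp26a1 (0.11 ± 0.264, adjusted p = 0.918) did not pass. Of 18 LXR targets 3 were lower and 1 higher than the sum (7 and 1 adjusted over the list alone, camera adjusted p = 0.000994, adjusted p = 0.669 with an estimated correlation). Pluripotency (0 of 24 called, 4 adjusted over the list alone) and immediate early genes (1 of 13, 3 adjusted over the list alone) had camera adjusted p = 0.000471 and 0.0148, with adjusted p = 0.997 for each with an estimated correlation. In all 23 genes were called, 1 higher and 22 lower, and 8 by 2-fold or more. Leaving out any of the other ES libraries in turn gave counts of 2 or 4 (ES control replicate 1 or 2), 2 or 3 (GW3965), 3 or 2 (LG268) and 4 (both-ligand replicate 1), while 1461 were called without both-ligand replicate 2. The calls of Lpcat3, Abcg1, Junb and Tmem160 ended without ES control replicate 1 (adjusted p = 0.192, 0.221, 0.221 and 0.226) or 2 (0.131, 0.131, 0.117 and 0.114), GW3965 replicate 1 (0.217 each) or 2 (0.0802, 0.104, 0.0802 and 0.0802), LG268 replicate 1 (0.147, 0.18, 0.147 and 0.147) or 2 (0.167, 0.166, 0.167 and 0.181), or both-ligand replicate 1 (0.154, 0.172, 0.127 and 0.157). Without both-ligand replicate 2 they held, and Mylip and Srebf1 passed (adjusted p = 0.0268 and 4.14e-05). In a fit of the 8 ES libraries Lpcat3, Junb and Tmem160 did not pass (adjusted p = 0.0655, 0.124 and 0.124), and with DESeq2 size factors Abcg1, Junb and Tmem160 did not (adjusted p = 0.0509 each), nor with the stricter filter (0.0522, 0.0522 and 0.0553). The count was 617 with no filter, 189 with the DESeq2 Wald test, 114 with limma-voom, and between 5 and 12 in a fit of the ES libraries, with GC and length offsets, with DESeq2 size factors and with the stricter filter.

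Responses that share the ES control libraries were set against each other. Of the genes higher with GW3965 and of those higher with LG268, 21 were higher with both, where independent draws would give 0.275. Simulated unchanged groups shared 0, but held only 0.0333 calls per comparison on average, too few to overlap. With both ligands together, 50 of the 53 genes higher with GW3965 and 80 of the 89 higher with LG268 were higher again (2.56 and 4.3 by independent draws), and 47 of the 57 lower with LG268 were lower again (3.69 by independent draws). Across genes, which are not independent replicates, the covariance of the GW3965 and LG268 log2 fold changes was 0.153, against 0.101 to 0.117 in 10 simulations with shared controls and no change. Their correlation was 0.503, against a simulated mean of 0.528. The 2 controls were not split, so part of the excess over independent draws may come from them.

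**Figure D3:**
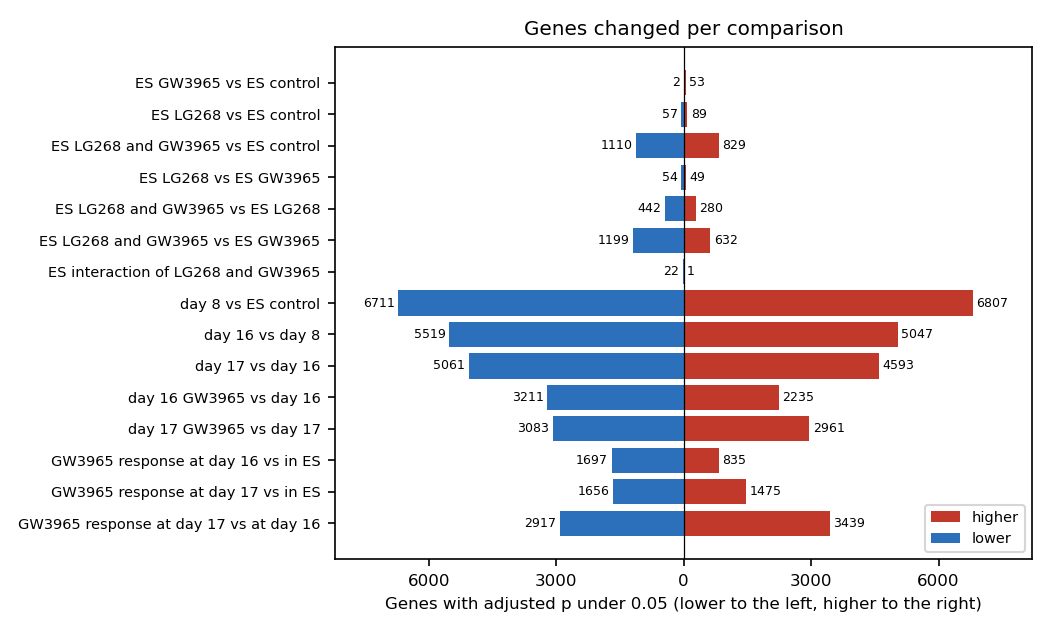
Number of genes called lower (left) and higher (right) in each of the 15 comparisons. The ES ligand comparisons ran from 23 to 1939 genes, and the comparisons between days and of GW3965 in differentiated cultures from 2532 to 13518.

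The step from ES cells to day 8 covered the embryoid body and retinoic acid phase of the protocol. Genes of the pluripotent state fell and genes of neurons and neural progenitors and Hox genes rose. With an estimated correlation 2 of the 11 list calls held, of pan-neuronal and endoderm genes. Pou5f1 (chromosome 17, 35506018 to 35510772), a core pluripotency factor gene, fell 80.7-fold from 698 ± 14.7 to 8.69 ± 1.06 CPM, and Nanog fell 83.9-fold from 358 ± 8.08 to 4.31 ± 1.01 CPM (adjusted p = 2.23e-17 and 6.08e-18). Tubb3 (chromosome 8, 123411424 to 123422015), a neuronal tubulin gene, rose 38.3-fold from 23 ± 0.504 to 882 ± 12.9 CPM, and Map2, a dendrite gene, rose 20.6-fold to 663 ± 19 CPM. Pax6, a neural progenitor factor gene, rose 37.8-fold to 65.4 ± 0.858 CPM, and Nes, the nestin gene, 1.68-fold from 179.5 ± 4.74 to 302 ± 0.311 CPM. The glutamate receptor gene Gria2 was at 122 ± 2.61 CPM and at 0 in ES control, at least 975-fold higher (floor of 3 counts per library), and Hoxb5, Hoxb6 and Hoxd3 were at least 902-fold, 859-fold and 677-fold higher. T, the mesoderm factor brachyury, fell 767-fold from 180 ± 8.32 to 0.227 ± 0.048 CPM.

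Of 24 pluripotency genes 23 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 1.27e-09, adjusted p = 0.0932 with an estimated correlation), with Tdgf1 302-fold lower. Of 22 pan-neuronal genes 21 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 1.23e-09, adjusted p = 0.0404 with an estimated correlation), with Dcx, a gene of migrating neurons, from 0.145 ± 0.0185 to 946 ± 19.1 CPM. Neural progenitor genes rose in 18 of 20 and fell in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 3.06e-05, adjusted p = 0.255 with an estimated correlation), with Fabp7 176-fold higher. Zic1 had 3 counts in the ES control libraries and rose 1240-fold with a counting interval of 423 to 6000. All 25 Hox genes rose (25 adjusted over the list alone, camera adjusted p = 7.11e-08, adjusted p = 0.0932 with an estimated correlation), with Hoxb9 at 299 ± 3.92 CPM. Retinoid targets rose in 19 of 22 and fell in 2 (the same adjusted over the list alone, camera adjusted p = 6.09e-05, adjusted p = 0.0932 with an estimated correlation), with Meis1 179-fold and Rarb 97.2-fold higher. Cell cycle genes fell in 20 of 21 and rose in 1 (the same adjusted over the list alone, camera adjusted p = 1.2e-07, adjusted p = 0.262 with an estimated correlation), with Bub1 4.265-fold lower.

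Other lineages appeared in the same cultures at day 8. Endoderm genes rose in 17 of 20 and fell in 1 (the same adjusted over the list alone, camera adjusted p = 6.09e-05, adjusted p = 0.0404 with an estimated correlation), with Gata4 15.2-fold higher at 82.7 ± 2.8 CPM. Mesenchyme genes rose in 11 of 15 and fell in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.413 with an estimated correlation), with the collagen gene Col3a1 212-fold higher at 995 ± 126 CPM. GABAergic genes rose in 11 of 13 and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.0932 with an estimated correlation), with Gad2 119-fold higher. Dopaminergic genes rose in 10 of 13 and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0227, adjusted p = 0.255 with an estimated correlation). Primed epiblast genes fell in 10 of 13 and rose in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.262 with an estimated correlation). In total 13518 genes changed, 6807 higher and 6711 lower, and 7489 by 2-fold or more. The largest falls besides T rested on 1 count at day 8, with Ms4a4d 745-fold lower (interval 133 to 29500), Cyp2j13 690-fold (123 to 27300) and Ubash3a 667-fold (119 to 26400).

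From day 8 to day 16 glial, mesenchyme and glutamatergic genes rose while Hox, neural progenitor and pan-neuronal genes fell, and 0 of the 11 list calls held with an estimated correlation. Olig1, an oligodendrocyte lineage gene, rose 97.6-fold from 0.269 ± 0.0571 to 26.4 ± 0.81 CPM, and the astrocyte gene Aldh1l1 rose 21.2-fold to 79 ± 8.19 CPM. Dcn, a gene of connective tissue, rose 13.05-fold from 51.3 ± 9.08 to 672 ± 70.8 CPM. Tubb3 fell 2.35-fold to 376 ± 13.5 CPM, Map2 1.79-fold to 370.2 ± 1.82 CPM, Nes 2.32-fold to 130 ± 9.4 CPM and Pax6 2.105-fold to 31.1 ± 3.34 CPM (adjusted p from 1.3e-10 to 1.72e-06). Pou5f1 rose 2.17-fold to 19 ± 4.14 CPM (adjusted p = 2.74e-05), and Nanog, at 5.74 ± 2.19 CPM, did not pass (adjusted p = 0.145) but did without day 16 replicate 2 (adjusted p = 0.00474) or with no filter (adjusted p = 0.0238). Several genes were at 0 at day 8 and at least 360-fold (Cyp2f2), 268-fold (Bpifb1) and 118-fold (Anxa10) higher at day 16. Krt13, an epithelial keratin gene with 1 count at day 8, rose 5130-fold with a counting interval of 920 to 203000. The largest falls were Stra8, 116-fold to 0.0962 ± 0.0197 CPM, Nr1h5, 28.1-fold, Prdm12, 23.0-fold, and Nepn, 19.4-fold.

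All 15 mesenchyme genes rose to day 16 (15 adjusted over the list alone, camera adjusted p = 4.3e-11, adjusted p = 0.0631 with an estimated correlation), with Postn 10.1-fold higher. Astrocyte genes rose in 9 of 12 and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 7.18e-05, adjusted p = 0.0631 with an estimated correlation). Oligodendrocyte genes rose in 10 of 12 with 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.000422, adjusted p = 0.322 with an estimated correlation). Glutamatergic genes rose in 10 of 14 and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00188, adjusted p = 0.0631 with an estimated correlation), with the NMDA receptor gene Grin1 6.31-fold higher. PPAR targets rose in 9 of 17 and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00547, adjusted p = 0.0688 with an estimated correlation). Immediate early genes rose in 8 of 13 and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.596 with an estimated correlation). Hox genes fell in 21 of 25 (22 adjusted over the list alone, camera adjusted p = 4.49e-10, adjusted p = 0.0631 with an estimated correlation), with Hoxb9 6.03-fold lower. Retinoid targets fell in 15 of 22 and rose in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 0.000577, adjusted p = 0.126 with an estimated correlation). Cell cycle genes fell in 19 of 21 with 0 higher (19 and 0 adjusted over the list alone, camera adjusted p = 5.45e-06, adjusted p = 0.427 with an estimated correlation). Neural progenitor genes fell in 13 of 20 and rose in 4, and pan-neuronal genes fell in 11 of 22 and rose in 4 (13 and 4, and 12 and 4, adjusted over the list alone), with camera adjusted p = 0.00613 and 0.00766, and adjusted p = 0.526 and 0.293 with an estimated correlation. In total 10566 genes changed, 5047 higher and 5519 lower (5356 and 5034 with DESeq2 size factors), and 3343 by 2-fold or more.

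From day 16 to day 17 genes of the immediate early and stress response rose, and genes of cholesterol synthesis and the cell cycle fell, but 0 of the 7 list calls held with an estimated correlation. Fos (chromosome 12, 85473890 to 85477273), an immediate early gene, rose 13.5-fold from 19.6 ± 0.691 to 265 ± 17.5 CPM (adjusted p = 1.4e-14), and Egr1 rose 7.47-fold to 496 ± 13.9 CPM. Fosb rose 49.0-fold to 68.3 CPM, Egr3 22.0-fold to 7.07 ± 2.5 CPM, and Apobr 18.3-fold to 44 ± 7.79 CPM. Trib3 (chromosome 2, 152337422 to 152344032), a gene of the integrated stress response, rose 15.5-fold from 13.4 ± 2.12 to 209 ± 9.12 CPM (adjusted p = 1.01e-13). Sqle, the squalene epoxidase gene, fell 2.54-fold from 155 ± 2.19 to 61 ± 0.521 CPM (adjusted p = 2.73e-14). The astrocyte gene Gfap rose 4.09-fold from 575 ± 19.4 to 2354 ± 249 CPM. The day 17 libraries were the 4 in which 31.84 to 33.53% of the reads stood apart as aligned more than once, so handling differed between these days.

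All 13 immediate early genes rose to day 17 and all 23 cholesterol synthesis genes and all 21 cell cycle genes fell (the same numbers adjusted over the list alone). Their camera adjusted p = 4.09e-10, 2.5e-12 and 4.07e-11 became adjusted p = 0.272, 0.272 and 0.341 with an estimated correlation. Top2a, a topoisomerase gene of dividing cells, fell 3.74-fold to 147 ± 2.99 CPM and Cdk1 2.93-fold. Stress and apoptosis genes rose in 13 of 17 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 3.97e-05, adjusted p = 0.341 with an estimated correlation), with Sesn2 2.76-fold higher and Ddit4 2.43-fold lower. Fatty acid synthesis genes fell in 11 of 16 and rose in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0217, adjusted p = 0.341 with an estimated correlation), with Fads2 4.17-fold lower. Pan-neuronal genes fell in 10 of 22 and rose in 1 (9 and 1 adjusted over the list alone), and astrocyte genes rose in 8 of 12 and fell in 3 (8 and 3 adjusted over the list alone), with camera adjusted p = 0.0217 and 0.0378, and adjusted p = 0.341 for each with an estimated correlation. Tubb3 fell 2.28-fold to 164 ± 18.2 CPM, Pax6 1.83-fold and Nes 1.45-fold, while Map2 did not pass (log2 0.10 ± 0.0557, adjusted p = 0.13). Pou5f1 fell 3.05-fold to 6.13 ± 0.261 CPM, and Nanog fell 1.48-fold (adjusted p = 0.0499), which ended without day 16 replicate 1 or day 17 replicate 2 (adjusted p = 0.602 and 0.458) and in a fit of the 4 libraries compared (adjusted p = 0.102), with the stricter filter (0.052) and with DESeq2 size factors (0.0502).

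In total 9654 genes changed from day 16 to day 17, 4593 higher and 5061 lower, and 2214 by 2-fold or more. The largest falls were in Entpd4, Srp54b and Erdr1, which were at 0 at day 17 and at least 566-fold, 189-fold and 149-fold lower (floor of 3 counts per library), and in Rpl31-ps12, 588-fold lower. Of the 50-mers of Entpd4, Srp54b and Rpl31-ps12, 100%, 92.9% and 72% occurred in a gene elsewhere, and Erdr1 had no such value. 

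At day 16 cultures with GW3965 were compared with those without. LXR targets and neuronal genes were higher, and mesenchyme, cell cycle and residual pluripotency genes lower. With an estimated correlation 3 of the 12 list calls held, all of neuronal lists. Abca1 rose 3.88-fold from 89.7 ± 4.03 to 347 ± 19.1 CPM (log2 1.95 ± 0.0781, adjusted p = 2.68e-12) and Abcg1 8.75-fold from 5.48 ± 0.113 to 47.8 ± 4.29 CPM (adjusted p = 1.22e-12). Srebf1 rose 2.60-fold to 355 ± 4.05 CPM and Mylip 2.35-fold to 36.2 ± 0.669 CPM (adjusted p = 6.86e-08 and 5.98e-08). Stmn2, a gene of growing axons, rose 1.77-fold from 333 ± 9.59 to 589 ± 1.53 CPM (adjusted p = 1.34e-08), and the synaptic vesicle gene Syp 2.10-fold to 198 ± 19.9 CPM (adjusted p = 3.3e-08). Gad1, which makes the transmitter GABA, rose 2.07-fold from 40.6 ± 0.902 to 83.8 ± 2.57 CPM, and Postn, a matrix gene, fell 2.33-fold from 336 ± 0.164 to 144 ± 19.6 CPM (adjusted p = 3.97e-08 and 1.72e-08).

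Of 22 pan-neuronal genes 18 rose and 1 fell at day 16 with GW3965 (19 and 2 adjusted over the list alone, camera adjusted p = 1.47e-16), of 14 glutamatergic genes 6 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.000571). Of 13 GABAergic genes 7 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.000208). These 3 calls held with an estimated correlation (adjusted p = 0.00656, 0.0435 and 0.0435). LXR targets rose in 11 of 18 and fell in 3 (11 and 4 adjusted over the list alone, camera adjusted p = 1.25e-05, adjusted p = 0.0642 with an estimated correlation). Fatty acid synthesis genes rose in 6 of 16 and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0063, adjusted p = 0.238 with an estimated correlation), with Scd2 2.04-fold higher. All 15 mesenchyme genes fell (15 adjusted over the list alone, camera adjusted p = 2.37e-12, adjusted p = 0.0527 with an estimated correlation), with Prrx1 2.645-fold lower. All 21 cell cycle genes fell (21 adjusted over the list alone, camera adjusted p = 2.97e-14, adjusted p = 0.125 with an estimated correlation), with Mcm5 1.70-fold lower. Neural progenitor genes fell in 12 of 20 with 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 0.000266, adjusted p = 0.275 with an estimated correlation), with Gli3 1.98-fold lower.

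Pluripotency genes fell in 14 of 24 and rose in 1 at day 16 with GW3965 (16 and 1 adjusted over the list alone, camera adjusted p = 0.000619, adjusted p = 0.28 with an estimated correlation), with Lin28a from 36.1 ± 13.7 to 5.265 ± 0.000591 CPM and Pou5f1 from 19 ± 4.14 to 4.28 ± 1.43 CPM (adjusted p = 6.91e-08 and 2.64e-07). Primed epiblast genes fell in 11 of 13 (11 adjusted over the list alone, camera adjusted p = 2.98e-05, adjusted p = 0.0671 with an estimated correlation). Retinoid targets fell in 11 of 22 and rose in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00124, adjusted p = 0.125 with an estimated correlation), with Crabp2 4.04-fold lower and Rarb 1.49-fold higher (adjusted p = 0.00146). Anterior neural genes fell in 4 of 9 (5 adjusted over the list alone, camera adjusted p = 0.0399, adjusted p = 0.308 with an estimated correlation). Cyp26a1 fell 1.76-fold (adjusted p = 0.00216), but did not pass without day 16 replicate 2 (adjusted p = 0.165). The largest rises besides Abcg1 were Cd93, 6.16-fold to 6.98 ± 1.6 CPM (adjusted p = 6.77e-07), Pnliprp1, 9.49-fold to 9.19 ± 11.2 CPM, and Rn45s, a ribosomal RNA precursor, 9.03-fold to 8850 ± 10800 CPM. The calls of the last 2 ended without 1 library, GW3965 replicate 1 for Pnliprp1 and replicate 2 for Rn45s. The largest falls were T, 77.5-fold (adjusted p = 2.01e-08), Myh3, 41.8-fold, Saa3, 17.1-fold (adjusted p = 0.000266), and Fabp1, 11.1-fold (adjusted p = 1.68e-05), and that of Myh3 ended without day 16 replicate 2 (adjusted p = 0.503) and with limma-voom (adjusted p = 0.0851). In total 5446 genes changed, 2235 higher and 3211 lower, and 648 by 2-fold or more. The 2 day 16 GW3965 libraries had the highest chi-square per gene (44.68, part of it from Rn45s). They correlated at 0.99314 and the both-ligand pair at 0.99245.

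At day 17 cultures with GW3965 were compared with those without, both with the same handling of reads. Lipid synthesis and cell cycle genes were higher, and immediate early and stress genes lower, but 0 of the 7 list calls held with an estimated correlation. Scd1 (chromosome 19, 44394455 to 44407879), a desaturase gene, rose 7.55-fold from 47.6 ± 1.5 to 360 ± 97.8 CPM (adjusted p = 9.79e-13). Abcg1 rose 5.02-fold to 24 ± 0.893 CPM, Srebf1 4.09-fold to 343 ± 9.22 CPM, Mylip 2.79-fold to 43.3 ± 1.9 CPM and Abca1 2.20-fold from 154 ± 1.48 to 339 ± 36.4 CPM (adjusted p from 2.35e-10 to 3.4e-09). Insig1, a sterol sensor gene, rose 3.02-fold to 119 ± 10.2 CPM (adjusted p = 3.44e-11). Fos fell 11.9-fold from 265 ± 17.5 to 22.1 ± 3.47 CPM, Fosb 56.1-fold to 1.22 ± 0.235 CPM, Trib3 12.3-fold to 17 ± 3.32 CPM and Trim66 16.7-fold to 2.48 ± 0.538 CPM (adjusted p from 4.45e-13 to 7.68e-09).

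All 23 cholesterol synthesis genes rose and all 13 immediate early genes fell at day 17 with GW3965 (the same adjusted over the list alone, camera adjusted p = 1.72e-18 and 2.27e-16, adjusted p = 0.0572 for each with an estimated correlation). Cell cycle genes rose in 20 of 21 with 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 2.65e-13, adjusted p = 0.21 with an estimated correlation), with Birc5 2.15-fold higher. Stress and apoptosis genes fell in 12 of 17 and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 3.72e-07, adjusted p = 0.21 with an estimated correlation), with Asns, the asparagine synthetase gene, 3.35-fold lower and Ddit4 2.54-fold higher. Fatty acid synthesis genes rose in 11 of 16 with 0 lower, and LXR targets rose in 10 of 18 and fell in 3 (12 and 0, and 11 and 3, adjusted over the list alone), with camera adjusted p = 6.12e-08 and 2.7e-06, and adjusted p = 0.0572 for each with an estimated correlation. Scd2 rose 3.60-fold to 4190 ± 314 CPM and Fasn 2.52-fold, while Lpl fell 1.82-fold. Oligodendrocyte genes rose in 7 of 12 with 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.00289, adjusted p = 0.379 with an estimated correlation), with Cnp 1.94-fold higher. Among 22 pan-neuronal genes 9 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.561), with Tubb3 1.90-fold higher and Thy1 2.32-fold lower. Rarb and Cyp26a1 did not pass (log2 0.31 ± 0.136 and 0.16 ± 0.191, adjusted p = 0.0849 and 0.547). The largest rises besides Scd1 were Ndufa4l2, 6.55-fold, Ankrd37, 5.86-fold, and Car3, 5.79-fold to 8.7 ± 7.44 CPM (adjusted p from 4.31e-07 to 0.000325). In total 6044 genes changed, 2961 higher and 3083 lower, and 870 by 2-fold or more.

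**Figure D4:**
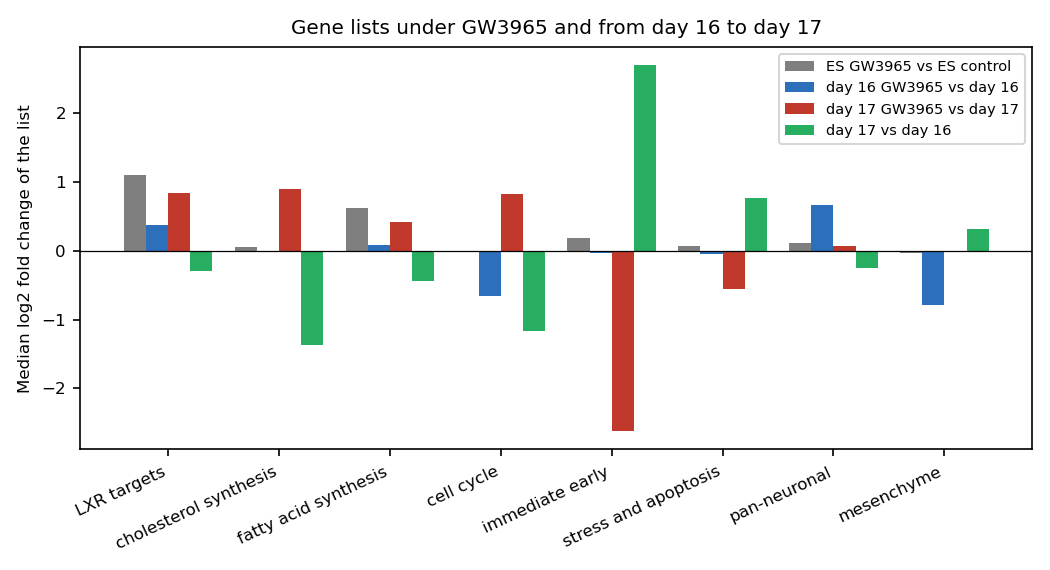
Median log2 fold change of 8 gene lists (bars) in 4 comparisons. Immediate early genes had a median of 2.69 from day 16 to day 17 and -2.62 with GW3965 at day 17, and cholesterol synthesis genes -1.37 and 0.897.

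The GW3965 response at day 16 was tested against that in ES cells, each relative to its own control. LXR targets and fatty acid genes responded less at day 16, and pan-neuronal genes more. Abca1 differed by a log2 of -3.42 ± 0.126 (adjusted p = 1.23e-12), Fasn by -1.87 ± 0.104, Mylip by -1.13 ± 0.149, Srebf1 by -1.09 ± 0.161, Acaca by -1.02 ± 0.085 and Scd2 by -0.90 ± 0.0767. Abcg1 (log2 0.05 ± 0.152, adjusted p = 0.881), Rarb (0.49 ± 0.357, adjusted p = 0.41) and Cyp26a1 (-0.59 ± 0.262, adjusted p = 0.147, but 0.0152 without day 16 replicate 1 and 0.0484 with no filter) did not pass. Of 18 LXR targets 13 were lower in the difference and 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 3.39e-10), as were 9 of 16 fatty acid synthesis genes (11 and 0 adjusted over the list alone, camera adjusted p = 8.84e-10) and 8 of 13 primed epiblast genes (10 and 0 adjusted over the list alone, camera adjusted p = 1.72e-07). Of 22 pan-neuronal genes 12 were higher (12 adjusted over the list alone, camera adjusted p = 2.75e-08), with Syp at 1.14 ± 0.132 and Stmn2 at 0.63 ± 0.078. These 4 calls held with an estimated correlation (adjusted p = 0.0336, 0.0336, 0.0359 and 0.0336).

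Cell cycle genes were lower in all 21 cases in that difference (21 adjusted over the list alone, camera adjusted p = 2.53e-19, adjusted p = 0.0811 with an estimated correlation), with Rrm2 at -1.08 ± 0.129. Pluripotency genes were lower in 12 of 24 (16 lower and 1 higher adjusted over the list alone, camera adjusted p = 9.83e-07, adjusted p = 0.155 with an estimated correlation), with Lin28a at -2.73 ± 0.284 and Pou5f1 at -2.22 ± 0.239. Mesenchyme genes were lower in 9 of 15 (11 adjusted over the list alone, camera adjusted p = 4.09e-06, adjusted p = 0.139 with an estimated correlation), with Col1a1 at -1.73 ± 0.232. Retinoid targets were lower in 8 of 22 cases and higher in 1 (9 and 1 adjusted over the list alone), neural progenitor genes lower in 5 of 20 (8 adjusted over the list alone) and GABAergic genes higher in 1 of 13 (1 adjusted over the list alone). Their camera adjusted p = 0.00838, 0.00436 and 0.0045 became adjusted p = 0.176, 0.409 and 0.0811 with an estimated correlation. The genes furthest apart were near the detection floor in 1 or more of the 4 groups. Wnt8a was at 1.46 ± 0.152 CPM at day 16 and 0 with GW3965 there, and Cer1 at 3.3 ± 0.973 and 0.0151 ± 0.0214 CPM (adjusted p = 8.34e-07 and 6.22e-06). Lin7a was at 26 ± 0.539 and 47.1 ± 3.5 CPM but under 0.1 CPM in ES cells (adjusted p = 0.0375, but 0.264 without ES control replicate 1, 0.0536 and 0.059 without day 16 replicate 1 or 2, and 0.198 and 0.0791 without ES GW3965 replicate 1 or 2). In total 2532 genes differed in response, 835 higher and 1697 lower, and 447 by 2-fold or more. Without ES control replicate 1, day 16 replicate 2, day 16 GW3965 replicate 2 or ES GW3965 replicate 1 the count was 1653, 1680, 1651 or 1566.

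At day 17 the GW3965 response differed from that in ES cells for 3131 genes, 1475 higher and 1656 lower, and 572 by 2-fold or more. Abca1 differed by a log2 of -4.24 ± 0.126 (adjusted p = 2.02e-14), Mylip by -0.88 ± 0.152, Fasn by -0.91 ± 0.104 and Acaca by -0.90 ± 0.088, while Scd1 responded more at day 17 by 1.07 ± 0.156. Abcg1 differed by -0.75 ± 0.178 (adjusted p = 0.0057, but 0.0697 without day 17 replicate 2), and Srebf1 (-0.43 ± 0.163, adjusted p = 0.0755, but 0.00174 in a fit of the 8 libraries compared), Rarb (0.22 ± 0.36, adjusted p = 0.736) and Cyp26a1 (0.39 ± 0.266, adjusted p = 0.357) did not pass. Of 23 cholesterol synthesis genes 22 were higher (22 adjusted over the list alone), with Sqle at 0.95 ± 0.0706. Of 21 cell cycle genes 19 were higher (20 adjusted over the list alone), with Birc5 at 1.14 ± 0.101. Of 13 immediate early genes 12 were lower (13 adjusted over the list alone), with Egr1 at -2.80 ± 0.144, Nr4a1 at -2.96 ± 0.161, Fos at -3.61 ± 0.217 and Fosb at -6.04 ± 0.549. Stress and apoptosis genes were lower in 11 of 17 cases and higher in 1 (12 and 1 adjusted over the list alone), with Trib3 at -3.74 ± 0.242, and LXR targets lower in 9 of 18 and higher in 1 (11 and 1 adjusted over the list alone). Their camera adjusted p = 8.53e-22, 3.02e-18, 1.31e-18, 2.21e-08 and 8.35e-06 became adjusted p = 0.057, 0.149, 0.057, 0.21 and 0.086 with an estimated correlation. Trim66 differed by -4.75 ± 0.503 (adjusted p = 2.16e-06), and Mixl1 was at 18.2 ± 2.99 CPM in ES control and 13.3 ± 0.735 with GW3965, but at 0 at day 17 and 0.457 ± 0.111 CPM with GW3965 there (adjusted p = 0.000615). Asic4, a channel gene near 0 in ES cells, was at 9.52 ± 1.26 CPM at day 17 and 5.03 ± 0.336 with GW3965 (adjusted p = 0.0108, but 0.0577 and 0.0714 without ES control replicate 1 or 2 and 0.0593 without ES GW3965 replicate 1).

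Between day 17 and day 16 the GW3965 responses differed for 6356 genes, 3439 higher at day 17 and 2917 lower (3221 and 3246 with DESeq2 size factors), and 1924 by 2-fold or more. The file names give a shorter treatment at day 17. Fos differed by a log2 of -3.58 ± 0.192, Nr4a1 by -3.11 ± 0.168, Trib3 by -4.12 ± 0.228, Fosb by -5.77 ± 0.462 and Trim66 by -5.63 ± 0.423. Scd1 responded more at day 17 by 1.78 ± 0.157 (adjusted p = 5.88e-08) and Srebf1 by 0.66 ± 0.163 (adjusted p = 0.00356), while Abca1 responded less by -0.82 ± 0.108 and Abcg1 by -0.80 ± 0.193 (adjusted p = 7.14e-06 and 0.00273). Mylip (0.25 ± 0.147, adjusted p = 0.202) and Rarb (-0.27 ± 0.185, adjusted p = 0.278) did not pass, and Cyp26a1 (0.98 ± 0.266, adjusted p = 0.00688) lost its call without day 16 replicate 2 (adjusted p = 0.0981). T differed by 6.84 ± 0.664 (adjusted p = 1.82e-07), Fabp1 by 4.79 ± 0.596 (adjusted p = 1.35e-05) and Myh3 by 7.97 ± 1.66 (adjusted p = 0.000807, but 0.152 without day 17 GW3965 replicate 2 and 0.0961 with limma-voom).

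By list, the response at day 17 was higher than at day 16 for all 21 cell cycle genes, with Bub1 at 2.14 ± 0.129, and for 22 of 23 cholesterol synthesis genes (21 and 22 adjusted over the list alone, camera adjusted p = 3.88e-18 and 3.85e-13, adjusted p = 0.0944 and 0.0933 with an estimated correlation). It was lower for 10 of 13 immediate early genes and for 18 of 22 pan-neuronal genes, of which 3 were higher (10, and 18 and 3, adjusted over the list alone, camera adjusted p = 1.13e-09 and 1.49e-08, adjusted p = 0.0953 and 0.0772 with an estimated correlation), with Syp at -1.32 ± 0.118. GABAergic genes were lower in 6 of 13 (6 adjusted over the list alone, camera adjusted p = 0.00118, adjusted p = 0.0933 with an estimated correlation), with Gad1 at -1.65 ± 0.122. Mesenchyme genes were higher in 10 of 15 and lower in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 8.89e-06, adjusted p = 0.158 with an estimated correlation), with Postn at 1.65 ± 0.118. Neural progenitor genes were higher in 12 of 20 (13 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.208 with an estimated correlation), with Vim at 1.20 ± 0.0891. In that difference 9 further lists had a camera adjusted p between 3.52e-05 (primed epiblast) and 0.0182 (nuclear receptors), and each lost its call with an estimated correlation (adjusted p from 0.0933 to 0.362).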

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

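Tests on shared 50-mers, handling at day 17, depth and offsets for GC content and length were chosen after the results were seen. So were those of opposite movement at day 17, of like LXR target levels and of LG268 and day 8. Leaving out 1 library and the 4-library fit were planned.

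The response to GW3965 differed between stages of culture. Stage was not separable from treatment length at day 16, where by the file names GW3965 was given from day 8 rather than for 24 h. Against ES cells 2532 genes differed at day 16 and 3131 at day 17, and 6356 differed between those days. At day 16 the log2 response was lower than in ES cells for Abca1 (-3.42), Fasn (-1.87), Mylip (-1.13), Srebf1 (-1.09), Acaca (-1.02) and Scd2 (-0.90). It was also lower for the proliferation gene Rrm2 (-1.08), the collagen gene Col1a1 (-1.73) and the pluripotency genes Lin28a (-2.73) and Pou5f1 (-2.22), and higher for the neuronal genes Syp (1.14) and Stmn2 (0.63).

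At day 17 the response fell short of that in ES cells for Abca1 (-4.24), Fasn (-0.91), Acaca (-0.90), Mylip (-0.88) and Abcg1 (-0.75), and exceeded it for Scd1 (1.07), Sqle (0.95) and Birc5 (1.14). Immediate early and stress genes were far lower: Fosb (-6.04), Trib3 (-3.74), Fos (-3.61), Nr4a1 (-2.96) and Egr1 (-2.80). So was Trim66 (-4.75). The difference between days 17 and 16 holds the same day 17 response, so the return of these genes there is not independent. In it Fosb was at -5.77, Trim66 at -5.63, Trib3 at -4.12, Fos at -3.58 and Nr4a1 at -3.11. Myh3 (7.97), T (6.84), Fabp1 (4.79), Bub1 (2.14), Scd1 (1.78), Postn (1.65), Vim (1.20), Cyp26a1 (0.98) and Srebf1 (0.66) responded more at day 17. Gad1 (-1.65), Syp (-1.32), Abca1 (-0.82) and Abcg1 (-0.80) responded less.

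Immediate early, stress, cholesterol synthesis and cell cycle genes moved in opposite directions from day 16 to day 17 and with GW3965 at day 17. Noise of the shared day 17 libraries was simulated from the fitted spread between libraries. Across all tested genes the covariance of the comparisons was -0.332, where simulation gave -0.0972 to -0.0825, so that spread alone does not account for it. Variation between cultures was not simulated if the replicates were technical, and the 4 lists were not tested apart. A state of the day 17 cultures without GW3965 stays open. For 4 of 4 lists the median in day 17 with GW3965 against day 16 was under 0.5 of that in day 17 against day 16, but choosing lists by opposite movement favours a smaller median.

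Reads of near-identical copies left uncounted at day 17 may explain the steepest falls from day 16. Of the falls of 16-fold or more with a value, 74.5% were genes with at least 10% of their 50-mers in a gene elsewhere, against 6.32% of all genes. They do not explain the comparison as a whole, since 55.4% of genes with under 1% of shared 50-mers changed. A difference in handling as such cannot be told apart from day, as 0 libraries of another day were handled that way.

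The number of genes changed with both ligands, 1939, could come from the libraries as well as from the ligands. Offsets for GC content and length gave 1683, of which 1247 were among the 1939, so such a trend does not explain it whole. Without replicate 1 the number was 727 and without replicate 2 it was 2844, but the 1 library left had no spread of its own, so 1 library standing apart stays open. Depth was 20 M counts on average, below the 28.15 M of the other ES libraries. The 4-library fit called 427, which is consistent with a spread between these libraries that the shared estimate understates.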

How the results depend on the processing

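The fits without the day 17 libraries and with offsets for GC content and length were chosen after results were seen. So was the readjustment over genes of few shared 50-mers, and the other settings were planned. The cause of each move was not tested.

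Without a filter on low counts, 164 genes changed with GW3965 in ES cells (55 in the report), 336 with LG268 (146), 266 between LG268 and GW3965 (103), 1373 between both ligands and LG268 (722) and 617 in the interaction (23). In fits of the groups compared the numbers were 369 for GW3965, 843 for LG268, 427 for both ligands (1939), 892 between LG268 and GW3965, 56 for both ligands against LG268, 111 against GW3965 (1831) and 5 in the interaction. With the DESeq2 Wald test they were 227 for LG268, 175 between LG268 and GW3965, and 189 in the interaction. The interaction also gave 12 genes with the stricter filter, 11 with DESeq2 size factors, 114 with limma-voom and 10 with GC and length offsets. Those offsets gave 1190 genes for both ligands against GW3965. The both-ligand reference reversed comparisons already given (1831 and 722 genes).

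Leaving out 1 library at a time gave 28 to 44 genes for GW3965 in ES cells, 42 to 70 for LG268, 718 to 2844 for both ligands, 29 to 35 between LG268 and GW3965, 103 to 2379 for both ligands against LG268, 325 to 3077 against GW3965 and 2 to 1461 for the interaction. The highest numbers of the 3 comparisons with both ligands and of the interaction came without both-ligand replicate 2. Ranges were 12569 to 12722 from ES cells to day 8, 9168 to 9571 to day 16, 8380 to 8526 to day 17, 3589 to 4880 for GW3965 at day 16 and 4335 to 4618 at day 17. Response differences ranged from 1566 to 2652 (day 16 against ES cells), 2224 to 2490 (day 17 against ES cells) and 5246 to 6237 (day 17 against day 16).

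With an estimated correlation, fewer lists were called in 14 of 15 comparisons. The numbers were 3 for GW3965 in ES cells (5 at the preset correlation), 5 for LG268 (7), 4 for both ligands (7), 5 between LG268 and GW3965 (8), 4 for both ligands against GW3965 (9) and 0 in the interaction (3). For the time course they were 2 to day 8 (11), 0 to day 16 (11) and 0 to day 17 (7). With GW3965 they were 3 at day 16 (12), 0 at day 17 (7), and 4, 0 and 0 for the response differences at day 16 against ES cells (10), day 17 against ES cells (5) and day 17 against day 16 (16). In a fit of the groups compared 11 lists were called for GW3965 at day 17.

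Of the named genes 384 of 386 kept their call with a replicate block, which moved 0 counts by more than 1.5 times (1808 genes for both ligands, 16 in the interaction). The calls it ended were Thy1 with GW3965 at day 16 (adjusted p = 0.0506) and Saa3 in the response difference at day 16 against ES cells (adjusted p = 0.0518). Calls stayed as reported in 1670 of 1828 cases of a named gene with 1 library left out. They stayed for 361 of 386 pairs in fits of the groups compared, 373 of 386 with limma-voom, 380 of 386 with DESeq2 size factors and 382 of 385 with the Wald test. They stayed for 93 of 93 genes among those with few shared 50-mers, for 272 of 275 without the day 17 libraries, and for 88 of 89 with GC and length offsets. In 0 cases did a direction turn for a gene called in either of the 2 fits, and turns of uncalled genes were not counted.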

Other observations

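Several genes not described above differed in the day 16 cultures. Gpr17 and Olig2, of oligodendrocyte precursors, rose 20.8-fold and 14.35-fold from day 8 (adjusted p = 4.14e-10 and 2.54e-10). Sparcl1, of astrocytes, rose 6.05-fold (adjusted p = 2.63e-15). The vesicular glutamate transporter gene Slc17a6 rose 4.44-fold from day 8 and a further 1.77-fold with GW3965 at day 16 (adjusted p = 1.71e-10 and 4.85e-05).

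With GW3965 the microtubule gene Mapt rose 1.78-fold at day 16 to 842 ± 19.9 CPM, while Gfap fell 2.985-fold and Aqp4, a water channel gene of astrocytes, 2.03-fold (adjusted p = 3.97e-08, 1.85e-06 and 1.16e-05). Of 12 astrocyte genes 5 fell and 1 rose, Clu from 184.3 to 334.1 CPM, and the list did not pass (camera adjusted p = 0.109). At day 17 Gpr17 rose 2.85-fold (adjusted p = 6.31e-05).

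Whether LG268 moves ES cells toward the day 8 state stayed open. Of the genes apart between LG268 and GW3965, 67.3% of those higher with LG268 and 75.9% of those lower moved the same way from ES control to day 8, against 49.9% and 49.7% of all genes. But 21 of the 54 lower genes were ones that GW3965 raised above ES control, so that share does not isolate LG268. Of the 49 higher genes GW3965 lowered 1, but the test needed both shares.

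GW3965 might have been thought to bring LXR targets to like levels whatever the level without it. The median distance between day 16 and ES levels of 11 targets was instead 1.23 in log2 with GW3965 and 0.593 without, although for Abca1 it went from 3.46 to 0.0469. The test was chosen after the levels were seen.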
